A study of Mus musculus with 8 samples.

How the data were processed

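Gene expression of mouse cells was measured on 8 Affymetrix oligonucleotide arrays of the Murine Genome U74 set. Of these, 4 were of the B design and 4 of the C design, which carry different probe sets. Per the labels' protocols, cells were sorted by flow cytometry and cultured for 3 days with 10% fetal bovine serum, 20 ng/ml stem cell factor, 30 ng/ml Flt3 ligand and 10 ng/ml interleukin-6, and biotinylated cRNA was made from 15 µg of total RNA and hybridised. The arrays were grouped by the tissue named in the labels, which gave 3 fetal liver arrays and 1 adult spleen array on each design. Fetal liver arrays 1, 2 and 3 and spleen array 1 are on the B design, and fetal liver arrays 4, 5 and 6 and spleen array 2 are on the C design. The numbers only name the arrays. The series text speaks of a larger number of cell types than the tissues in the labels, so the fetal liver arrays may hold more than 1 cell type, and they were not split.

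The deposited values are an intensity for each probe set, a linear MAS5 signal per the submitters' processing notes, with 1 column per array. The MAS5 version, its scaling target and detection calls are not given in the sources used here. The deposited columns were not on a common scale. Their medians on the B design were 48.4, 8.3 and 21.3 for fetal liver arrays 1, 2 and 3 and 26.1 for the spleen array, and on the C design 5.3, 29.55 and 10.0 for fetal liver arrays 4, 5 and 6 and 14.0 for the spleen array. The number of arrays limits the precision. No array held the same values as another.

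The test designs, the alternatives, the 20 gene lists and the rule for named genes were set before the data were examined. Under that rule the deposited scaling would have been kept had the trimmed means, with 2% taken off each end, lain within 10% of each other. They did not, and the values of each design were quantile normalised. The values were then taken as log2(value + offset), with the 25th percentile of the design's values as the offset (8.525 on the B design and 4.975 on the C design). Fold changes are on this scale, which understates the change of low signals. Probe sets whose mean over the 4 arrays reached the design's median value were tested (26.075 on the B design and 14.65 on the C design). A gene low in fetal liver was thus tested only where its spleen signal was high enough, and the reverse. The 66 Affymetrix control probe sets of each design were left out.

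Fetal liver was compared with adult spleen per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 spleen array per design, the model had 2 residual degrees of freedom and assumed that the lone spleen array varies like the fetal liver arrays. Nothing in the labels says that the fetal liver arrays came from separate animals or cultures. The p-values of single probe sets thus measure only the spread between these arrays. That spread may be technical, and it may include differences between cell types that the labels do not assign. The SD given with n = 3 is likewise over arrays. A count without a test was also made, of probe sets whose spleen signal lay at least 2-fold outside all 3 fetal liver arrays, and it was repeated with each fetal liver array in the place of the spleen array. The 20 lists were of the angiopoietin family and Mfap4, secreted factors known from stem cell niches, fetal and imprinted genes, and genes of hepatocytes, erythroid cells, T cells, cytotoxic and NK cells, B cells, MHC class II and antigen presentation, granulocytes, macrophages, mast cells and basophils, megakaryocytes and platelets, endothelium, stroma and extracellular matrix, cell cycle and DNA replication, the interferon response, blood stem and progenitor cells, the stress and immediate early response, and sex-linked genes. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and limma's fry as alternatives. At that preset camera treats genes as nearly independent, so its p-values reflect the genes in a list more than the spread between arrays. On the B design the estimated correlation was 0.84 for erythroid and 0.926 for granulocyte genes, but -0.025 for T cell and -0.014 for macrophage genes. With an estimated correlation camera uses at most the model's 2 residual degrees of freedom, so it has little power and not passing there decides little. A list used 1 probe set per gene, the one with the highest mean.

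Gene symbols came from the platform's annotation. On the B design 10581 probe sets had 1 symbol, 178 had several and 1652 had none, and on the C design these counts were 7717, 150 and 4001. The gene identifier matched a current reference table for 10550 and 7677 of the probe sets with 1 symbol, and none of these symbols needed an update. The fit covered 6528 probe sets on the B design, of 4647 named genes, and 6292 on the C design, of 3613 named genes. Probe sets whose identifiers end in f, s or g before "at" can detect related transcripts. Those that end in r or i did not meet the full rules for choosing probes. The assignment of all of these is uncertain.

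The named genes were, for each design, the 10 with the largest fold change in each direction among those past the threshold. Where fewer passed, the direction was filled up with the genes of the largest gap between the spleen array and the nearest fetal liver array. Up to 4 members of each gene list were added by the same gap, along with every measured member of the angiopoietin list. Clone and locus names and probe sets with several symbols were left out. The alternatives were the authors' scaling, division by the array median, 2 other offsets, 2 other filters, leaving out each fetal liver array in turn, 2 other variance models, 2 other fold limits, and for lists the estimated correlation, fry and the mean of a gene's probe sets.

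The fit was tested on simulated data, in 20 runs per design with 200 changed probe sets each. For the B design it recovered 0.149%, 1.72% and 70.1% of log2 changes of 1, 2 and 4, and 6.31% of its calls were false. For the C design it recovered 0%, 0% and 0.0758% of changes of those sizes. Lists shifted by 1 on the log2 scale were found in 100% of cases on both designs, and 0.333% and 0.667% of unshifted lists were called on the B and C designs. These simulated genes varied independently, which the genes of a real list do not. The simulated lists were also larger than every list tested here except cell cycle and DNA replication. A smaller list that did not pass may therefore still be shifted.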

Results

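The data were 8 array measurements of sorted mouse cells cultured for 3 days, 6 from fetal liver and 2 from adult spleen. Fetal liver is the main site of blood formation before birth, and blood stem cells expand there. The study asked which secreted proteins, angiopoietin-like proteins among them, let blood stem cells expand in culture. Each of the 2 array designs held 3 fetal liver arrays and 1 spleen array and was compared within itself. The deposited column medians ranged from 8.3 to 48.4 on the B design and from 5.3 to 29.55 on the C design, so signals are given after quantile normalisation. No detection calls were used here, and whether a low signal lies above background is unknown.

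The first comparison asked which transcripts differed between fetal liver and adult spleen cells on the B design. The adult spleen array carried more signal of T cell genes. Ms4a4b, a membrane protein of T cells, had a signal of 3822 in spleen against a mean of 36.6 ± 12.4 (SD, n = 3) in fetal liver, and its log2 fold change was -6.44 (SE 0.528, limma adjusted p = 0.0207). Cd3e, a chain of the T cell receptor complex, had 291 in spleen against 5.94 ± 3.1 (SD, n = 3), with a log2 fold change of -4.39 (SE 0.507, limma adjusted p = 0.0352). In the other direction Arhgap19 had 261 ± 22.7 (SD, n = 3) in fetal liver against 4.75 in spleen, a log2 fold change of 4.34 (SE 0.479, limma adjusted p = 0.0289). Pbk, a mitotic kinase, and Cit, a kinase of cytokinesis, were also higher in fetal liver, with log2 fold changes of 3.82 and 3.94 and a limma adjusted p of 0.0424 each.

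Of the 6528 probe sets tested on the B design, 39 passed the threshold. Of these, 34 were higher in spleen, from 28 named genes, and 5 were higher in fetal liver, from 5 genes. After Ms4a4b, the largest differences toward spleen were those of Kbtbd11 (log2 fold change -6.27), Gimap3 (-5.43), Satb1 (-5.32), Gpr18 (-4.99), Pik3ip1 (-4.97), Dapl1 (-4.81), Nlrc5 (-4.63), Als2cl (-4.60) and Foxo1 (-4.55). Gimap3 belongs to a family of lymphocyte GTPases, Satb1 organises chromatin in thymocytes, and Nlrc5 activates MHC class I genes. The Ms4a4b and Satb1 probe sets are of a kind that can detect related transcripts, and those of Dapl1 and Apoa1 likewise. Another Satb1 probe set, not of that kind, had a log2 fold change of -4.42. The probe set of Pik3ip1 ends in i, so its assignment is uncertain too. Of the 4 tested probe sets of Pik3ip1, 0 were higher in fetal liver. A second tested probe set of Foxo1 went the other way, with a log2 fold change of 0.24 (limma adjusted p = 0.945). Hacd1 (3.55) and Nmral1 (3.42) completed the genes higher in fetal liver. The next genes by the gap to the spleen array did not pass. They were Stfa3 (log2 fold change 6.43, limma adjusted p = 0.131), Olfm4 (5.18, adjusted p = 0.121), Apoa1 (5.75, adjusted p = 0.0849), Cenpf (3.50, adjusted p = 0.0703) and Spc24 (3.23, adjusted p = 0.0535). The count of 39 fell to 0 without fetal liver array 1 and to 0 without array 2, and rose to 340 without array 3. These p-values measure only the spread between these arrays, with the lone spleen array assumed to vary like the fetal liver arrays. The count was also 0 under the authors' scaling and 0 without the filter on low signals.

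**Figure D1:**
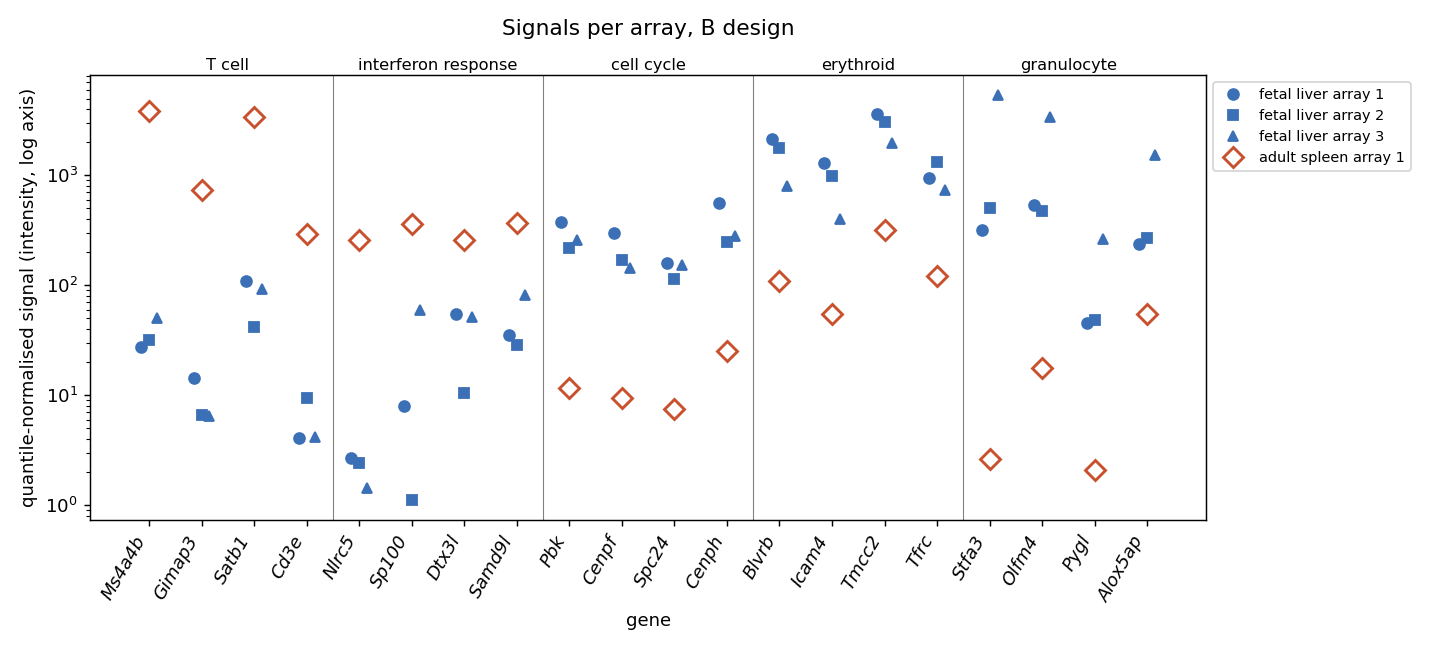
Quantile-normalised signal (intensity, log axis) of 20 genes on the B design, the 4 members of each of 5 gene lists with the widest gap between tissues, with 1 filled symbol for each fetal liver array and an open diamond for the spleen array. The spleen array lies above all 3 fetal liver arrays for the T cell and interferon genes and below them for the others, as for Cd3e at 291 and Pbk at 11.8.

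The spleen array lay at least 2-fold outside all 3 fetal liver arrays for 729 probe sets on the B design, above them for 373 and below them for 356. The same count with a fetal liver array in its place was 138 for array 1, 561 for array 2 and 205 for array 3. The spleen array had the highest value for 27.1% and the lowest for 30.9% of tested probe sets, where 25% each would come from arrays in random order. Under the authors' scaling the count was 390, with 294 above and 96 below, and without fetal liver array 3 it was 1180. Under the authors' scaling the median log2 fold change of all tested probe sets was -0.26, against 0.03 after quantile normalisation.

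Among the B design's lists that passed camera, T cell genes were the most uniform in direction, though not in size. Of 34 list genes on the array 29 were tested. The mean used by the filter includes the spleen array, so genes low in fetal liver were tested only where spleen was high. This may add to the uniform direction. All 29 tested members were lower in every fetal liver array than in the spleen array, with a median log2 fold change of -2.88. Over all genes 9 of them passed the threshold, and 25 did when adjusted over the list alone. The list passed camera (adjusted p = 2.34e-30), but not with an estimated correlation (adjusted p = 0.0785 with an estimated correlation). Interferon response genes were shifted the same way, 20 of 23 toward spleen with a median of -1.77 (camera adjusted p = 1.34e-10, and adjusted p = 0.269 with an estimated correlation). Nlrc5 was the 1 member called over all genes, and 11 passed when adjusted over the list alone. Sp100 had signals of 7.98, 1.13 and 60.1 in fetal liver arrays 1, 2 and 3 against 362 in spleen.

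Cell cycle and DNA replication genes were shifted toward fetal liver, 47 of 49 members with a median log2 fold change of 1.70 (camera adjusted p = 1.33e-20, and adjusted p = 0.269 with an estimated correlation). Pbk was called over all genes, and 27 members passed when adjusted over the list alone. Cenph, a kinetochore protein whose probe set can detect related transcripts, had a mean signal of 366 ± 174 (SD, n = 3) in fetal liver and 25.15 in spleen. Erythroid genes were shifted toward fetal liver as well, 23 of 24 with a median of 2.20 (camera adjusted p = 4.32e-12, and adjusted p = 0.6 with an estimated correlation). None was called over all genes and 12 passed when adjusted over the list alone. Blvrb, a reductase of red cells, had 1575 ± 698 (SD, n = 3) against 110 in spleen, and the blood group protein Icam4 had 897 ± 458 (SD, n = 3) against 54.8. Tmcc2 had a log2 fold change of 3.09 and the transferrin receptor Tfrc 2.91, with limma adjusted p of 0.0835 and 0.0912.

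Granulocyte genes were shifted toward fetal liver for 10 of 11 members, with a median of 2.11 (camera adjusted p = 5.02e-04, and adjusted p = 0.6 with an estimated correlation). None was called over all genes, and 4 passed when adjusted over the list alone. All 11 had their highest signal in fetal liver array 3, and without that array the list's median was 1.20. Stfa3, a cystatin of neutrophil precursors, had signals of 320, 501 and 5376 in fetal liver arrays 1, 2 and 3 against 2.65 in spleen, and Olfm4, a neutrophil granule protein, had 536, 471 and 3369 against 17.9. Macrophage genes were shifted for 14 of 18 members with a median of 0.73 (camera adjusted p = 0.00397, and adjusted p = 0.269 with an estimated correlation). None was called over all genes, and 5 passed when adjusted over the list alone. Csf2rb, a cytokine receptor chain, had 238, 107 and 1305 in fetal liver arrays 1, 2 and 3 against 8.63 in spleen.

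The other lists tested on the B design did not pass camera. Their median log2 fold changes were 0.91 for 7 hepatocyte genes (adjusted p = 0.132), -0.07 for 9 blood stem and progenitor cell genes (adjusted p = 0.132), 0.37 for 14 endothelial genes (adjusted p = 0.145), 0.35 for 6 secreted niche factors (adjusted p = 0.191), 0.07 for 12 megakaryocyte and platelet genes (adjusted p = 0.802), 0.20 for 6 stromal genes (adjusted p = 0.802) and 0.21 for 6 stress genes (adjusted p = 0.957). For 8 B cell genes the median was 0.07 while camera's direction and the mean of -0.23 were negative (adjusted p = 0.802). Of the blood stem and progenitor cell genes, Satb1 and Trib2 were called higher in spleen, and Satb1 is also in the T cell list. Their mean of -0.82 lay further from 0 than their median, and the stress genes had a mean of -0.004 beside a positive median. When adjusted over the list alone, 1 gene each passed in the hepatocyte, niche factor, B cell and stress lists, 2 in the blood stem and progenitor cell list, and 0 in the others. Some of these lists passed in an alternative. The hepatocyte list passed without fetal liver array 3 and under the authors' scaling (adjusted p = 0.00265 and 0.00303, range 0.00265 to 0.6 over all alternatives), and so did the endothelial list (adjusted p = 0.0277 and 0.037, range 0.0277 to 0.998). The blood stem and progenitor cell list passed with the filter at the 75th percentile (median -0.49, adjusted p = 0.0218, range 0.0218 to 0.823) and the B cell list without the filter (median -0.47, adjusted p = 0.039, range 0.039 to 0.998). Leaving out 1 fetal liver array moved these medians. Without array 1 the hepatocyte median was 0.47, the endothelial 0.78, the B cell 0.34, the megakaryocyte and platelet 0.15, the stromal 1.07, the stress 0.39 and the blood stem and progenitor cell -0.40. Without array 2 the niche factor median was 0.03, the B cell 0.13, the megakaryocyte and platelet -0.29, the stromal -0.16 and the blood stem and progenitor cell 0.07. Without array 3 the endothelial median was 0.67, the B cell 0.04, the megakaryocyte and platelet 0.23, the stromal 0.42 and the blood stem and progenitor cell -0.65. Too few genes were tested for the lists of fetal and imprinted genes (3), MHC class II genes (3), cytotoxic and NK cell genes (1), mast cell genes (1) and sex-linked genes (0). The medians of the first 4 of these were 0.01, 0.39, -1.34 and 1.08, and for MHC class II genes the mean was -0.01.

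The same comparison on the C design covered other probe sets. None of 6292 passed the threshold in limma. All adjusted p were at least 0.18, and 392 had an unadjusted p under 0.05, where 314.6 would come by chance. With a fetal liver array in the place of the spleen array, that count was 919 for array 4, 160 for array 5 and 165 for array 6. The lowest adjusted p was that of Izumo1r, a folate receptor family member of regulatory T cells, at 490 in spleen against 1.64 ± 0.44 (SD, n = 3) in fetal liver (log2 fold change -6.23, SE 0.54). The next genes toward spleen, by the gap between the spleen array and the nearest fetal liver array, were Slfn8 (-4.53), Gramd3 (-4.45), Iglv1 (-3.99), Bach2 (-4.40), Macf1 (-3.49), Rhof (-3.51), Ccnd3 (-3.36), Ripor2 (-3.50) and Slc2a4rg-ps (-3.21). Toward fetal liver they were Lyz1 (3.99), Fads2 (3.54), Hacd1 (3.54), Fn3k (4.20), Lyl1 (3.06), Diaph3 (3.23), Catsper2 (3.39), Slc4a1 (3.04), Arhgap23 (3.39) and Mtrf1 (2.33). Lyl1, a transcription factor of blood progenitors, had 1578 ± 478 (SD, n = 3) in fetal liver against 180 in spleen, and Slc4a1, the anion exchanger of red cells, had 826 ± 473 (SD, n = 3) against 86.6. The probe sets of Izumo1r, Gramd3, Iglv1, Lyz1, Fads2, Fn3k and Lyl1 can detect related transcripts. Those of Ccnd3, Ripor2, Slc2a4rg-ps, Hacd1 and Slc4a1 end in r or i, so their assignment is uncertain too. In simulated data of this spread the test recovered 0.0758% of log2 changes of 4, so single genes could hardly pass.

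On the C design the spleen array lay at least 2-fold outside all 3 fetal liver arrays for 510 probe sets, above for 250 and below for 260. In its place fetal liver array 4 gave 891, array 5 gave 260 and array 6 gave 263. The spleen array was highest for 24.3% and lowest for 25.8% of tested probe sets, where 25% each would come from arrays in random order. Under the authors' scaling the count was 244, with 166 above and 78 below, and the median of all tested probe sets was -0.26. Without fetal liver array 5 it was 820 and without array 6 it was 881.

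The lists passed camera on the C design in 7 cases. With an estimated correlation each had a camera adjusted p of 0.297, and none passed. For the fetal and imprinted (-0.168), interferon (-0.159) and macrophage (-0.017) lists the estimate was below the preset 0.01, so a higher correlation was not the reason there. It was above 0.01 for the others. T cell genes had a median log2 fold change of -1.95, 7 of 8 toward spleen (camera adjusted p = 1.26e-05), and 3 passed when adjusted over the list alone. Ets1, a lymphocyte transcription factor, had 536 in spleen against 44.4 ± 25.5 (SD, n = 3), and Gata3 had 109 against 25.2 ± 11.4 (SD, n = 3). Interferon response genes had a median of -0.98, 6 of 6 toward spleen (camera adjusted p = 0.00297), with Irf7 at 693 in spleen against 202 ± 34.3 (SD, n = 3). Cell cycle and DNA replication genes had a median of 0.75, 33 of 40 toward fetal liver (camera adjusted p = 1.15e-05), with Aurkb at 88.95 ± 15.96 (SD, n = 3) against 22.1. Erythroid genes had a median of 1.26, 12 of 14 toward fetal liver (camera adjusted p = 5.48e-05), and Alad, an enzyme of haem synthesis, had 260 ± 174 (SD, n = 3) against 19.95. Hepatocyte genes had a median of 0.98, 10 of 11 (camera adjusted p = 0.00216), fetal and imprinted genes 0.92, 5 of 6 (camera adjusted p = 0.0298), and macrophage genes 0.35, 12 of 16 (camera adjusted p = 0.0298). In these 6 lists other than the T cell list, 0 genes passed when adjusted over the list alone. The fetal and imprinted list did not pass without fetal liver array 4 (adjusted p = 0.0652, range 0.0267 to 0.297 over all alternatives), nor the macrophage list without array 6 (adjusted p = 0.11, range 0.00164 to 0.345). The median of the macrophage list was 0.82 without fetal liver array 4, 0.59 without array 5 and 0.27 without array 6. The probe sets named here for Gata3, Irf7 and Aurkb can detect related transcripts, and that of Alad ends in i, so its assignment is uncertain too.

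Other lists on the C design did not pass. The median was 0.79 for 11 granulocyte genes and 0.37 for 9 megakaryocyte and platelet genes (camera adjusted p = 0.0972 each), and without fetal liver array 4 they had adjusted p of 0.0351 and 0.0475, over ranges of 4.65e-04 to 0.529 and 0.029 to 0.564 in all alternatives. Both also passed under the authors' scaling (adjusted p = 4.65e-04 and 0.029), as did the endothelial list (adjusted p = 0.0379, range 0.0379 to 0.403), and the granulocyte list passed with the filter at the 75th percentile (adjusted p = 0.00109). It was -0.20 for 8 endothelial genes (adjusted p = 0.113), 0.20 for 6 niche factors and -0.22 for 7 stress genes (adjusted p = 0.359 each). For 7 blood stem and progenitor cell genes it was -0.09 while camera's direction was positive (adjusted p = 0.613), and for 19 stromal genes it was -0.24 with camera's direction again positive (adjusted p = 0.978). Without array 4 the megakaryocyte and platelet median was 0.90, the endothelial -0.38, the stromal -0.07 and the blood stem and progenitor cell -0.30. Without array 5 the megakaryocyte and platelet median was 0.81, the niche factor 0.60, the endothelial -0.32, the stromal -0.41 and the blood stem and progenitor cell -0.24. Without array 6 the megakaryocyte and platelet median was 0.18, the niche factor 0.53, the stromal -0.10, the stress -0.14 and the blood stem and progenitor cell 0.02. When adjusted over the list alone, Lyl1 passed in the blood stem and progenitor cell list, Ets1 in the endothelial list, which shares it with the T cell list, and Bach2 in the B cell list. Too few were tested of the B cell (4), cytotoxic (3), MHC class II (3), mast cell (1) and sex-linked (0) genes. The medians of the first 4 of these were 0.32, -0.22, -0.37 and 1.30, and for B cell genes the mean was -0.58.

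Members of the angiopoietin family were examined on their own, since the study is about them. The list was drawn up from the study's subject, so its direction is not independent evidence. Angptl6 had a mean signal of 67.6 ± 8.39 (SD, n = 3) in fetal liver and 23.45 in spleen on the B design, a log2 fold change of 1.24 (limma adjusted p = 0.35). Angptl7 had 76.8 ± 18.4 (SD, n = 3) against 24.3 on the B design, a log2 fold change of 1.35 (limma adjusted p = 0.34). On the C design it had 41.0 ± 5.74 (SD, n = 3) against 15.85, a log2 fold change of 1.13 (limma adjusted p = 0.838). On the B design adjustment was also made over the list alone. With 2 genes tested it hardly changes a p-value, so its outcome adds no support. No gene of the list passed over all genes. Angpt1 on the C design had 24.99 ± 11.05 (SD, n = 3) against 17.0, and Angptl1, below the signal limit for testing, had 11.3 ± 7.25 (SD, n = 3) against 19.8. The probe set of Angptl6 can detect related transcripts. Those of Angptl7 on the C design and of Angptl1 end in r, so their assignment is uncertain too. Angptl2 and Angptl3 were not analysed here.

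Fetal liver arrays differed from each other as well. Across tested probe sets, which are not independent replicates, Pearson's r between fetal liver arrays was 0.74 (arrays 1 and 2), 0.76 (1 and 3) and 0.66 (2 and 3) on the B design and 0.71 (4 and 5), 0.70 (4 and 6) and 0.80 (5 and 6) on the C design. The spleen array's r with fetal liver arrays 1, 2 and 3 was 0.54, 0.44 and 0.61, and that of the other spleen array with arrays 4, 5 and 6 was 0.62, 0.75 and 0.76. Erythroid genes were above their mean over the arrays in fetal liver arrays 1 and 2, by a median of 0.85 and 0.76 on the log2 scale, and stood at -0.20 in array 3. On the C design they stood at 0.83, 0.68 and -0.22 in arrays 4, 5 and 6. Granulocyte genes stood at -0.15, 0.05 and 1.39 in arrays 1, 2 and 3, and at -0.298, 0.205 and 1.001 in arrays 4, 5 and 6.

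**Figure D2:**
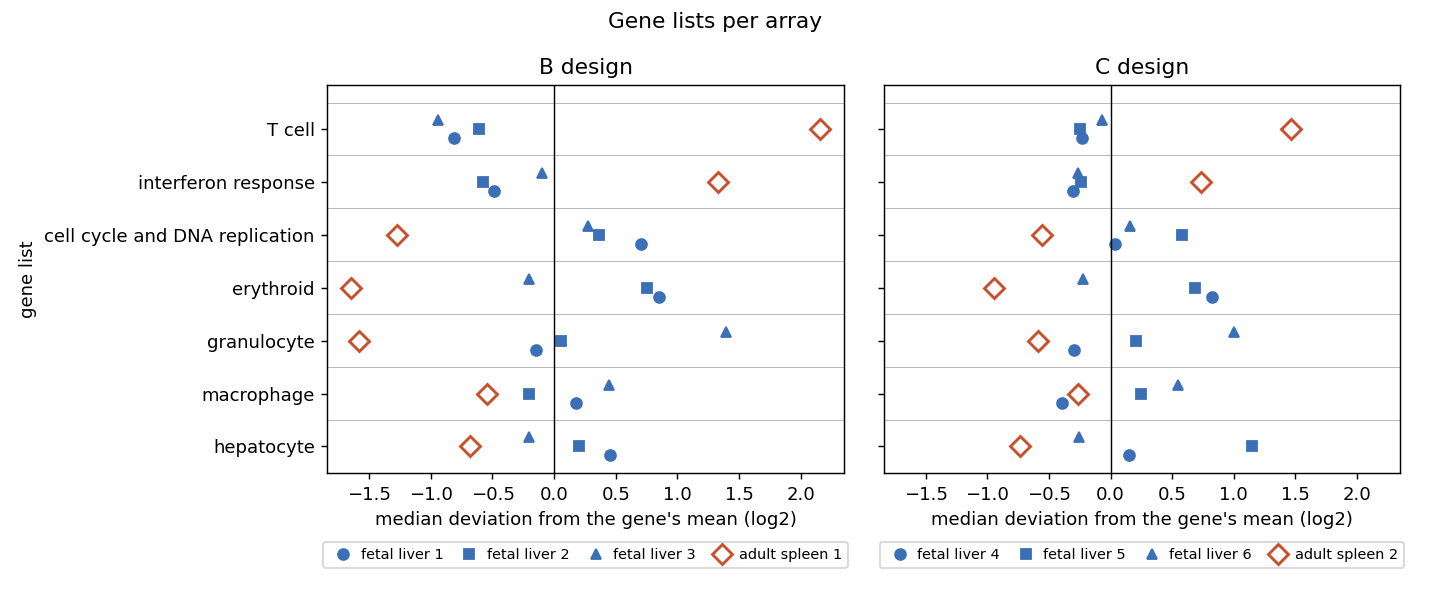
Median deviation of each gene list from its genes' mean over the 4 arrays (log2), by list, with 1 filled symbol for each fetal liver array and an open diamond for the spleen array, B design on the left and C design on the right. The spleen array is highest for the T cell list, at 2.16 and 1.47, and fetal liver arrays 3 and 6 are highest for the granulocyte list, at 1.393 and 1.001.

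Both designs measured 1011 genes in common by different probe sets. Across these genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.48 and Spearman's rho of 0.37, and 59.55% had the same sign. Of 88 genes that differed at least 2-fold on both, 79 had the same sign. Hacd1 was one of them, at 3.55 and 3.54. The labels do not say whether the arrays of the designs shared RNA. Deposited signals of the 3' Gapdh control paired the arrays across designs. They were 6448.8 and 8428.3 in arrays 1 and 5, and 1113.7 and 1272.5 in arrays 2 and 4. Arrays 3 and 6 had 4490.4 and 4143.2, and the spleen arrays 1853.3 and 2226.5. Deviations of the common genes from their mean paired the same arrays except 2 and 4 (Pearson's r 0.12, against 0.16 for arrays 2 and 5). The same RNA may thus lie on both designs, and agreement between them cannot be taken as independent evidence. The numbers in the array titles share their first 4 digits between the spleen arrays and with no fetal liver array that has a number. The title of fetal liver array 1 holds no number, and what these digits mean is not stated. A difference between hybridisation runs and the difference between tissues thus cannot be told apart.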

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

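No paired analysis was possible because the labels give no replicate numbers. The first 4 digits of the title numbers could not be used as a random block on the C design, since only 1 pair of arrays shares them and limma gave no correlation estimate, and that alternative was not run. On the B design the 39 called probe sets became 0 under the authors' scaling, 11 with arrays divided by their median (all 11 among the 39), 8 with the offset at the 10th percentile (all 8 among them), 71 with the offset at the median (39 shared), 0 without the filter and 24 with a variance trend (22 shared). Leaving out a fetal liver array gave between 0 (without array 1 or array 2) and 340 (without array 3, 39 shared). It was 39 with robust variances and 48 with the filter at the 75th percentile, 29 of them shared. On the C design the count was 0 in every alternative run. The spleen array's count on the B design, 729, became 390 under the authors' scaling, 415 with the filter at the 75th percentile, 1407 at 1.5-fold and 168 at 4-fold, and between 909 and 1180 with a fetal liver array left out, which widens the count by construction. That on the C design, 510, became 244 under the authors' scaling, 304 with the offset at the median, 228 with the filter at the 75th percentile, 1022 at 1.5-fold and 87 at 4-fold, and between 723 and 881 with an array left out. The 6 lists passing on the B design became 0 with an estimated correlation and 1 with fry (T cell, fry adjusted p = 0.00323, range 2.25e-46 to 0.0785 over all alternatives), and 6 to 8 with an array left out, and were 8 under the authors' scaling and 8 without the filter. The 7 on the C design became 0 with an estimated correlation and 0 with fry, and 6 to 8 with an array left out. They were 10 under the authors' scaling and 5 without the filter, where the interferon (adjusted p = 0.0723) and the fetal and imprinted list (adjusted p = 0.2945) did not pass, over ranges of 0.00109 to 0.297 and 0.0267 to 0.297 in all alternatives. The median correlation between fetal liver arrays was 0.835 without the filter and 0.667 with the filter at the 75th percentile on the B design, against 0.736, and 0.811 without the filter on the C design, against 0.711. The lists that passed camera, 6 on the B design and 7 on the C design, kept the sign of their median in every alternative run, while among the 8 and 7 that were tested and did not pass, the median changed sign in some alternative for 6 and 4. Among named genes, the sign changed in 1 case, Chac1 under the authors' scaling (log2 fold change -0.055 against 0.28, called in neither). Except where the construction is named, the cause was not tested. Fetal liver arrays 2 and 4 had the lowest deposited medians, 8.3 and 5.3, and without detection calls it is unknown which of their signals lie above background.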

Other observations

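The test on array brightness, the count of shared title numbers, the test on the C design's fetal liver array 6 and the test on granulocyte genes picked without array 3 were chosen only after the results they bear on were seen.

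Several transcripts were uneven among fetal liver arrays. Cldn13, Nxpe2 and Ppbp were chosen after their values were seen. Cldn13, a claudin of red cell precursors, had signals of 1408, 5376 and 12.9 in fetal liver arrays 1, 2 and 3 and 26.5 in spleen array 1. Nxpe2 had 580, 3822 and 10.4 against 21.15, and the platelet chemokine Ppbp had 407, 1953 and 9.55 against 18.8. Of the hepatocyte list, the fibrinogen chain Fga had 19.3, 221 and 25.7 in fetal liver arrays 4, 5 and 6 and 9.28 in spleen array 2. The apolipoprotein Apoa1, also among the B design's named genes, had 1526, 886 and 204 in arrays 1, 2 and 3 and 3.83 in spleen. The 18S ribosomal RNA control stood at 19.6, 211 and 3.19 times the array median in fetal liver arrays 1, 2 and 3 and at 3.17 times in the spleen array. On the C design it was 358, 53.2 and 6.21 times in arrays 4, 5 and 6 and 4.5 times in the spleen array.

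T cell genes were low in every fetal liver array of the B design. Lower brightness of the array was examined in the fetal liver array of each design that was brighter than the spleen array. These were array 1 (deposited median 48.4 against 26.1) and array 5 (29.55 against 14.0). Because both were picked for being brighter, the outcome could not have favoured lower brightness and decides nothing about it. In array 1, 0 of 29 T cell genes, 0%, reached the spleen array's deposited signal, so the difference there was present before normalisation. In array 5 the share was 3 of 8, 37.5%, which missed the bound of under 10% and decides nothing. The dimmer arrays 2, 3, 4 and 6 were not tested in this way. Quantile normalisation removes an evenly lower brightness, yet after it the list still stood at -0.61 and -0.94 in arrays 2 and 3, against 2.16 in the spleen array. This argues against an evenly lower brightness of arrays 2 and 3. A loss of weak signals in them stays open, as does lower brightness of arrays 4 and 6. The first 4 digits of the title numbers, the part used here, held both tissues in 0 cases. Array 1 has no number in its title. That the spleen arrays were run apart from the fetal liver arrays thus also stays open. The difference between the tissues or the sorted cells remains among the open explanations and was not tested apart from it.

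Granulocyte genes were high and erythroid genes low in fetal liver array 3 and, on other probe sets, in array 6, whose title number has the same first 4 digits but differs in the rest. A fault of a single hybridisation stays open, since the excess of array 6 over the next fetal liver array in granulocyte minus erythroid median on the C design, 1.70 on the log2 scale (0.48 to 3.35 by resampling genes), compares single arrays and resamples genes that vary together (estimated correlation of the granulocyte list 0.349 on the C design and 0.926 on the B design). For noise of weak probe sets, the excess of array 3 on the B design, 3.28 (1.84 to 4.12) at or above the 75th percentile of mean signal, decides nothing, since array 3 is part of that mean, but with 7 granulocyte genes picked by the other arrays and 20 erythroid genes picked by array 3, a choice that works against the pattern, the excess was 3.23 (1.57 to 4.08), which argues against noise that is independent between genes. A different cell type, a preparation or run that these arrays share, or the state of their RNA may account for the pattern, and none of these was tested. Of the fetal liver arrays of their designs, arrays 3 and 6 had the lowest 18S control over the median (3.19 and 6.21) and the highest 3' to 5' ratio of the control for Tfrc, itself in the erythroid list (4.62 and 6.25), while in array 3 the Actb and Gapdh ratios (1.18 and 0.967) were the highest of its design and in array 6 those ratios (1.05 and 0.95) were below those of array 4 (1.11 and 0.985).

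Fetal liver array 2 on the B design and array 4 on the C design, the dimmest of each, lay at least 2-fold outside the other arrays for 561 and 891 probe sets, against at most 205 and 263 for other fetal liver arrays. Low signal may be the cause, and in the brightest of 4 equal groups of tested probe sets the share outside was 1.604 times that of the next fetal liver array on the B design and 2.42 times on the C design. Low signal alone was set to give under 1.5 on both and another cause at least 2 on both, so it stays open. In the weakest group the shares were 11.3% for array 2 and 17.1% for array 4, and in the brightest 4.72% and 7.69%. Arrays 2 and 4 also had the highest 18S control over the array median of their designs, at 211 and 358 times. The first 4 digits of their title numbers are the same, and array 5 has them too. Whether their RNA or a shared run was the cause was not tested, nor was any biological explanation.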
